A study of Mus musculus with 8 samples.

How the data were processed

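RNA was extracted from whole heart ventricle of mouse embryos at embryonic day 14.5 and made into libraries with a directional (strand-keeping) Illumina kit, per the labels' protocols. The control embryos carried floxed Lem2 alleles (gene symbol Lemd2, an inner nuclear membrane protein), and the conditional knockout (cKO) embryos carried in addition a Cre transgene labelled XMLC2V. The labels list 4 control and 4 cKO samples. The deposited table holds estimated counts per gene, which the authors listed for 15358 genes with symbol, position and strand. STAR 2.4.2a, HTSeq 0.6.1 and the genome build mm10 are named in the submitters' processing notes, with no role or order. Which step gave values that are not whole, and whether reads were counted by strand, is not given in the sources used here. Of all values, 30.3% were not whole, so the deposited estimated counts were rounded before any count test.

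Each library column was matched to a sample by the code in its title. The last value column matched no title and equalled the sum of the 7 library columns in all 15358 genes (tolerance 1e-06 counts), so it was taken as a row sum and not used as a library. Control replicate 4 was therefore not analysed here, and the comparison rests on 3 control and 4 cKO libraries in place of the 4 and 4 planned. No gene of the mitochondrial chromosome was among the genes listed. Library totals ran from 28921922 to 39351262 counts. Libraries of one group correlated at r = 0.991 to 0.995 on log2 CPM across genes, which are not independent replicates. Libraries of different groups correlated at r = 0.9897 to 0.9939, so the ranges overlap and r does not part the groups. Counts of libraries of one group differed with a variance 9.39 to 13.1 times that of sampling noise, so no library stood for another. The ratio is the chi-square per degree of freedom over genes with at least 10 counts. The labels call the controls littermates and name no litter, so p-values measure the spread between these samples.

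Genes with low counts were removed with filterByExpr of edgeR 4.0.16 (minimum count 10), which left 14887 genes and removed 471. Library sizes were scaled by TMM. Control and cKO libraries were compared with edgeR's quasi-likelihood F-test (glmQLFit and glmQLFTest, R 4.3.3) and Benjamini-Hochberg adjustment over all genes tested, with a threshold of 0.05. Log2 fold changes are cKO over control, with their standard errors (SE), and levels are TMM-scaled CPM (counts relative to library size), mean ± SD. Lemd2 was also tested with an exact two-sided permutation test of log2 CPM (prior count 2) over the 35 arrangements of 7 libraries into 3 and 4.

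For groups of genes, 41 lists were fixed before the data were examined, as were the tests and the rule for named genes. The 39 lists with at least 5 tested members, the sex-linked genes aside, were tested with camera of limma 3.58.1 at a preset correlation of 0.01 and Benjamini-Hochberg adjustment over lists. Camera with an estimated correlation, and fry, were run beside it. The list of mitochondrially encoded genes had no member in the table. List members were also adjusted over the list alone. Named are Lemd2, the 12 largest rises and 12 largest falls among called genes whose groups do not overlap (average log2 CPM of at least 0, with predicted genes, clone symbols and sex-linked genes left out), up to 4 members with the smallest p of each list described, a fixed set of nuclear envelope, p53, cardiac and DNA-sensing genes, the sex-linked genes, and the 5 smallest p in each direction. Other genes named were chosen after their values were seen, and are said to be so. Some genes that meet the rule are not reported here.

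Alternatives were DESeq2 size factors, upper-quartile factors, no low-count filter, DESeq2 1.42.0, limma-voom, the replicate number as a block, the code in the titles (F169 or F191, not explained by the labels) as a term or F169 alone, Y-linked expression as a term, and each library left out in turn. Leaving out the 2 cKO libraries that express Xist was added after the data were seen. The edgeR step was tested on simulated counts for 14781 genes with the means and sizes of these libraries. Of genes changed 1.25-fold, 61.2% were called, against 73.1% at 1.5-fold and 81.2% at 2-fold. Of 14583 unchanged genes 12 were called, beside 41, 49 and 52 of the genes changed 1.25-fold, 1.5-fold and 2-fold. In that simulation the false share of the calls thus lay above the threshold of 0.05. With no gene changed 0 were called.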

Results

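The transcriptome of the heart ventricle was measured by RNA-seq at embryonic day 14.5 in embryos in which Lem2 was targeted with a Cre transgene and in control littermates with floxed alleles alone. The question was which genes differ in the ventricle once Lem2, a protein of the inner nuclear membrane that binds the lamina and chromatin, is targeted there. The libraries held 34667532, 39351262 and 35679259 counts in control replicates 1 to 3. The cKO replicates 1 to 4 held 29290338, 37967877, 28921922 and 37213081 counts. Xist, the RNA that coats the inactive X chromosome of females, reached 1324 CPM in cKO replicate 3 and 1102 CPM in cKO replicate 4. It was at most 0.504 CPM in the other 5 libraries. The Y-linked gene Ddx3y lay at 102, 105 and 88.0 CPM in the controls and at 80.4 and 98.0 CPM in cKO replicates 1 and 2, against 0.0346 and 0.0543 CPM in cKO replicates 3 and 4. The groups thus differed in sex as well as in genotype, since all 3 controls carried Y-linked expression.

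Lemd2, the targeted gene (mm10 chromosome 17, 27189600 to 27204439, minus strand), fell from 35.9 ± 1.28 CPM in control to 16.4 ± 2.01 CPM in cKO ventricle (SD, 3 and 4 libraries). The log2 fold change was -1.13 (SE 0.086; adjusted p = 0.00135, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Each of the 4 cKO libraries was below each control, at 38.2 to 51.5% of the control mean. The exact two-sided permutation test gave p = 0.0286, the smallest that 35 arrangements allow. Whole-gene counts include cells in which no allele was deleted and any transcript that lacks only the floxed part.

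Of 14887 genes tested, 162 differed between cKO and control, 114 higher and 48 lower in cKO (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Among called genes with an average log2 CPM of at least 0, the largest rise was in Gdf15, a secreted stress cytokine. Gdf15 went from 1.07 ± 0.499 to 3.67 ± 0.598 CPM (log2 fold change 1.78, SE 0.27, adjusted p = 0.023 by edgeR). Its call was lost without control replicate 2 (adjusted p = 0.0865) or 3 (0.0693), without cKO replicate 2 (0.0751) or 3 (0.0653), within F169 (0.115), with Y-linked expression as a term (0.108) and without the 2 Xist-expressing libraries (0.149), with log2 fold changes from 1.463 to 2.208 over all alternatives. Among genes with an average log2 CPM of at least 0 that the naming rule takes, Gdf15 was followed by Lgals3 (1.55, SE 0.25), the lysosomal glycoprotein Gpnmb (2.20 ± 0.358 to 5.20 ± 1.29 CPM), the AP-1 subunit Fos (1.23, SE 0.13) and Cyr61, a matricellular target of YAP (1.20, SE 0.11). Arrdc3 rose from 105 ± 5.17 to 187 ± 13.3 CPM (log2 0.83, SE 0.060, adjusted p = 0.00135 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Slc16a6 rose by 0.87, the BMP antagonist Nog by 0.90, Gadd45b by 0.89 and Gadd45g by 0.73 on the log2 scale. Btg3, an antiproliferative factor, was also among the smallest p-values (0.40, SE 0.035).

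After Lemd2 the largest fall among called genes that the naming rule takes was in Gt(ROSA)26Sor, the non-coding transcript of the Rosa26 locus (chromosome 6, 113067429 to 113077245). Its level went from 69.5 ± 7.44 to 35.6 ± 3.23 CPM (log2 -0.96, SE 0.083). Adra1d, an alpha-1 adrenergic receptor, fell by 0.78 and Kcnn1, a calcium-activated potassium channel, by 0.67. The transcription factors Tox (-0.59) and Nr3c2, the mineralocorticoid receptor (-0.55), were lower as well. Plppr1 (-0.62), Atcayos (-0.57), Rnf207 (-0.51), Ppp1r26 (-0.47) and Adamts6 (-0.46) were also among the 12 largest falls. Calcoco1 (-0.37, SE 0.042) and the pyruvate dehydrogenase kinase Pdk2 (-0.40, SE 0.046) had smaller falls with small errors. Among the called genes that the naming rule takes, Gt(ROSA)26Sor, Slc16a6, Atcayos, Rnf207, Pln and Kcnq1 overlap another tested gene on the opposite strand. Their counts are uncertain because the counting strand is not stated. Cep85l, which overlaps Pln, had a mean of 8.05 CPM, against 1682 CPM for Pln in control and 1409 CPM in cKO. Btg3 overlaps Gm7334 (mean 4.19 CPM) on the same strand, so its counts are uncertain whichever way strands were counted.

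Changes were modest: the median absolute log2 fold change of the called genes was 0.333, and 20 genes were at least 1.5-fold higher and 6 at least 1.5-fold lower. At an unadjusted p under 0.05 there were 2665 genes. The count fell to 17 without the 2 Xist-expressing libraries and to 20 with Y-linked expression as a term, and was 20 within F169, while F191 holds 1 library per group and allows no test. Without control replicate 1, 2 or 3 it was 43, 37 or 42, and without cKO replicate 1, 2, 3 or 4 it was 133, 28, 41 or 83. The number of genes called rose to 214 with the F code as a term and to 637 with DESeq2. Of the 39 called genes besides Lemd2 that the naming rule takes, 14 were called whichever single library was left out, among them Gt(ROSA)26Sor, Cyr61, Fos, Arrdc3, Cdkn1a and Etv5. Atcayos, Spred1, Zfp36 and Kcnq1 lost their call in each of the 7 cases, and Gpnmb, Adra1d, Kcnn1, Plppr1, Nr3c2, Sdf2l1, Etv4, Dusp6, Mthfd2, Psat1, Aars and C1qb in 6. Lgals3, Nog, Adamts6 and Pln lost it in 5 cases, Gdf15 in 4, Gadd45g and Eda2r in 3, and Rnf207 and Ccng1 in 2. Without the 2 Xist-expressing libraries 9 of the 39 were called: Fos, Cyr61, Gadd45b, Slc16a6, Arrdc3, Eda2r, Gt(ROSA)26Sor, Etv5 and Btg3.

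**Figure D1:**
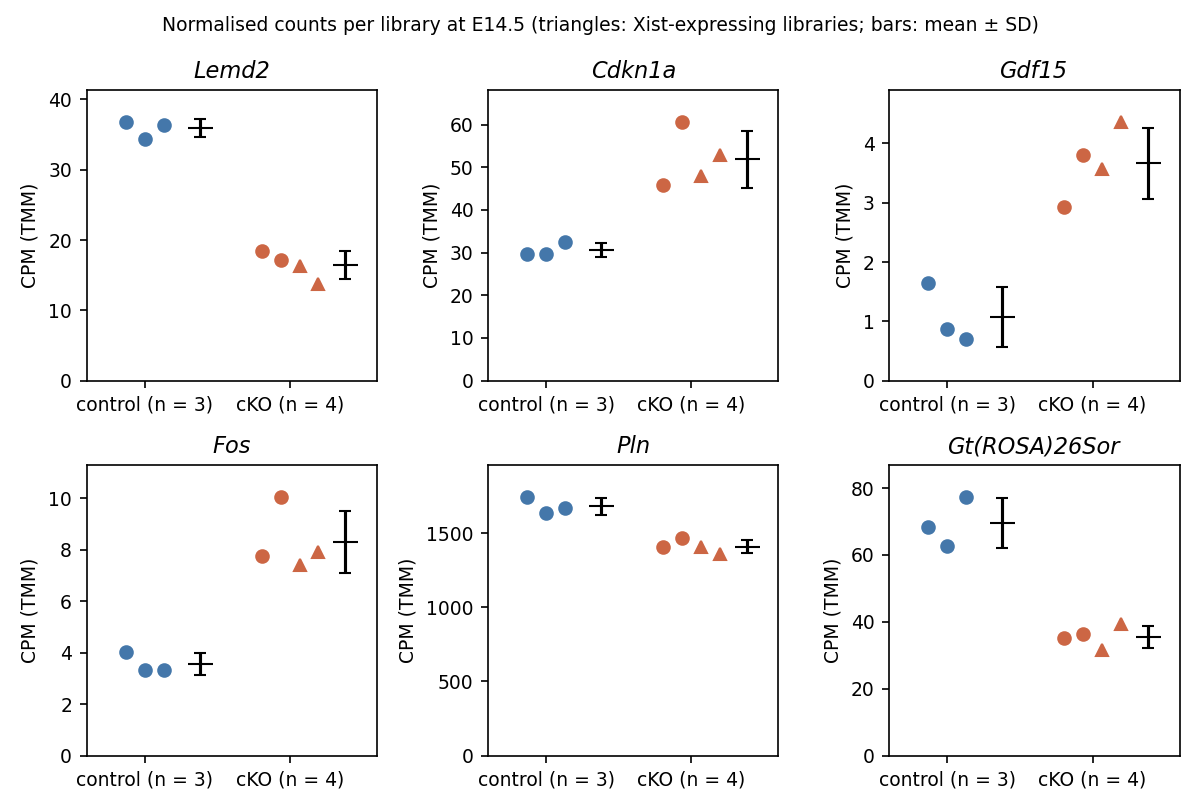
TMM-scaled counts per library size (CPM, vertical axes) of 6 genes in each control (blue, n = 3) and cKO library (orange, n = 4), with triangles for the 2 cKO libraries that express Xist and bars for the mean ± SD. Lemd2 lies at 16.4 CPM on average in cKO against 35.9 in control, Gt(ROSA)26Sor at 35.6 against 69.5, and the cKO libraries lie apart from the controls in every panel.

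Targets of the tumour suppressor p53 were higher as a list in cKO ventricle. Camera of limma called the list higher at an adjusted p of 1.37e-08, against an adjusted p of 0.359 with an estimated correlation (unadjusted p = 0.0158). Of 39 tested members 8 were higher and 0 lower over all genes, and 19 were higher and 0 lower when adjusted over the list alone, with a median log2 fold change of 0.162. Cdkn1a, the cyclin-dependent kinase inhibitor p21, rose from 30.6 ± 1.57 to 51.8 ± 6.59 CPM (log2 0.76, SE 0.090, adjusted p = 0.00733 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Ccng1, a p53-induced cyclin, rose by 0.33 (SE 0.043) and the receptor Eda2r by 0.73 (SE 0.10). Phlda3 (0.35), Epha2 (0.46), Plk2 (0.44) and the pro-apoptotic Pmaip1 (0.73), chosen after their values were seen, and Gdf15 were the other members called. Mdm2, the p53 ubiquitin ligase, had 0.17 (SE 0.042, adjusted p = 0.0916 by edgeR with Benjamini-Hochberg adjustment), and Trp53 itself had -0.03 (SE 0.040). The p53 list was the list fry called (adjusted p = 0.0379). Without the 2 Xist-expressing libraries the list median was 0.169 and camera's adjusted p was 2.01e-09, but only Eda2r and Epha2 of the 8 called members were still called (adjusted p = 0.0393 for each by edgeR). Cdkn1a then had 0.80 (SE 0.109, adjusted p = 0.075 by edgeR) and Gdf15 1.66 (SE 0.332, adjusted p = 0.149).

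**Figure D2:**
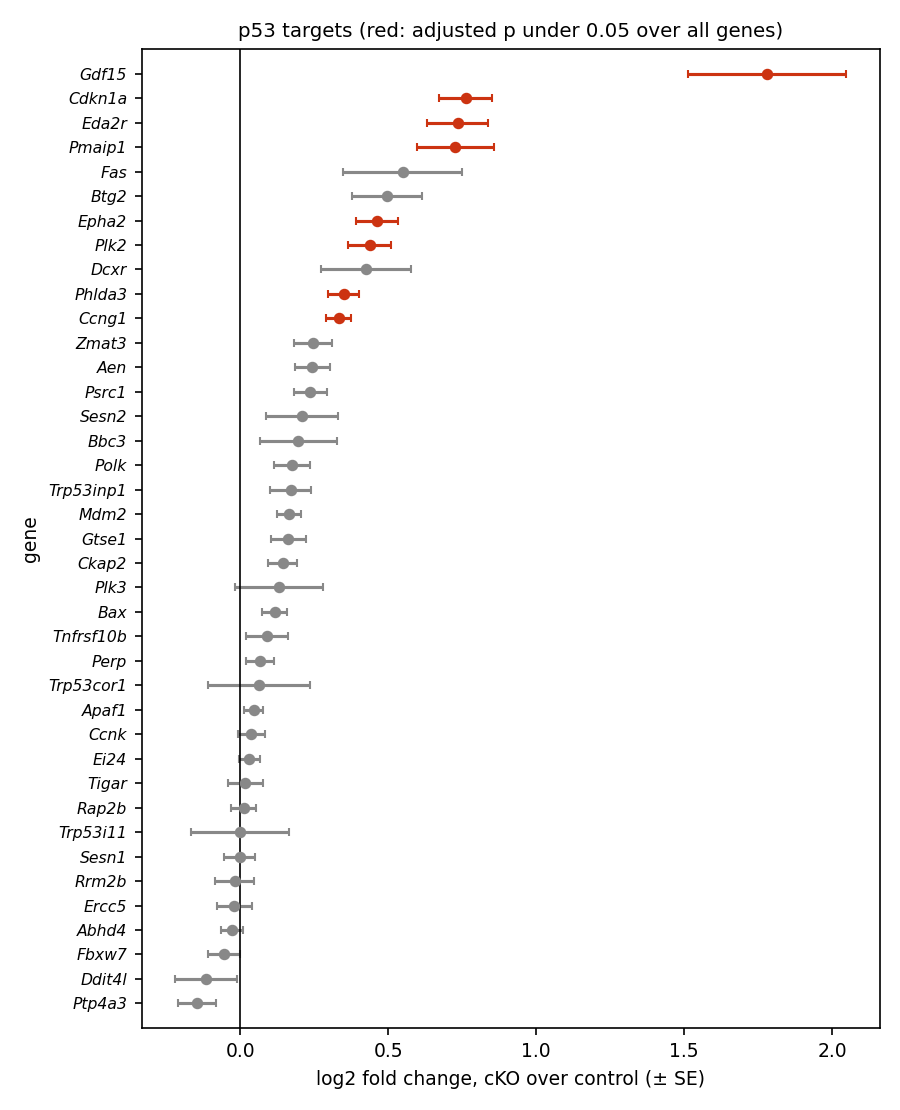
Log2 fold change of cKO over control (horizontal axis, point) with its standard error (bar) for the 39 tested p53 targets (vertical axis), in red where the adjusted p over all genes was under 0.05. The 8 called members are all above 0, led by Gdf15 at 1.78, and 32 of the 39 members lie above 0.

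Genes of the unfolded protein response, which restore folding in the endoplasmic reticulum, were higher as a list (adjusted p = 2.04e-07 by camera, and an adjusted p of 0.608 with an estimated correlation), with 1 of 20 members higher over all genes, 14 adjusted over the list alone and none lower. The called member was Sdf2l1 (0.31, SE 0.054), and the chaperones Calr (0.20), Hsp90b1 (0.19) and Hspa5 (0.20, SE 0.048) did not pass over all genes. Targets of ATF4, the effector of the integrated stress response, were higher as well (adjusted p = 6.36e-05 by camera, and an adjusted p of 0.608 with an estimated correlation). Of 29 members 13 were higher and 1 lower adjusted over the list alone, and 3 were higher over all genes. These were the serine and one-carbon enzymes Mthfd2 (0.38, SE 0.063) and Psat1 (0.30, SE 0.057) and the alanyl-tRNA synthetase Aars (0.20, SE 0.039).

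Feedback targets of ERK signalling were higher as a list (adjusted p = 1.27e-06 by camera, and an adjusted p of 0.608 with an estimated correlation). Of 15 tested members 5 were higher over all genes and 8 adjusted over the list alone, among them the ETS factors Etv5 (0.49, SE 0.059) and Etv4 (0.48, SE 0.075), the ERK phosphatase Dusp6 (0.30, SE 0.051) and Spred1 (0.20, SE 0.038). Immediate early genes, the first to be transcribed after a stimulus, were higher too (adjusted p = 1.13e-05 by camera, and an adjusted p of 0.608 with an estimated correlation), with 2 of 17 members higher over all genes and 9 adjusted over the list alone. These 2 were Fos and Zfp36 (0.50, SE 0.098), and Junb (0.43, SE 0.12) and Egr3 (0.99, SE 0.30) did not pass over all genes.

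Among cardiac genes, the transcription factors were lower as a list (adjusted p = 0.00244 by camera, and an adjusted p of 0.514 with an estimated correlation). Of 22 members 0 passed over all genes (9 at an unadjusted p under 0.05, and 6 called by DESeq2) and 8 were lower adjusted over the list alone, led by Zfpm2 (-0.17, SE 0.039), Mef2d (-0.23, SE 0.055), Mef2a (-0.14, SE 0.036) and the ventricular factor Irx4 (-0.25, SE 0.067). Fetal and stress markers were higher as a list (adjusted p = 0.0035 by camera, and an adjusted p of 0.662 with an estimated correlation), with 1 of 18 members called over all genes, Gdf15, and 7 adjusted over the list alone. Natriuretic peptide transcripts lay at 1228 ± 153 CPM in control and 1902 ± 339 CPM in cKO for Nppa (0.63, SE 0.13, adjusted p = 0.061) and at 104 ± 29.5 and 171 ± 32.2 CPM for Nppb (0.72, SE 0.18, adjusted p = 0.0931), by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Ctgf (0.91, SE 0.18), Spp1 (1.63, SE 0.34) and Ankrd1 (0.49, SE 0.16) did not pass either. Within F169 the fetal list was not called (median 0.104, adjusted p = 0.0867 by camera).

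Calcium handling and channel genes held 2 called falls among 29 members, Pln, the phospholamban that restrains the calcium pump of the sarcoplasmic reticulum (1682 ± 58.0 to 1409 ± 44.8 CPM, log2 -0.26, SE 0.040), and the potassium channel Kcnq1 (-0.32, SE 0.062). Adjusted over the list alone, 6 were lower and 2 higher, and camera did not call the list (median -0.101, adjusted p = 0.0611, and an adjusted p of 0.84 with an estimated correlation). Camera called it lower with limma-voom (median -0.0924, adjusted p = 0.0168) and without control replicate 2 (-0.132, 0.00307), cKO replicate 2 (-0.118, 0.0129) or cKO replicate 3 (-0.125, 0.0272), while the median was -0.0231 within F169. Fatty acid uptake and oxidation was lower as a list (adjusted p = 0.00321 by camera, and an adjusted p of 0.693 with an estimated correlation), with 0 of 24 members called over all genes (7 at an unadjusted p under 0.05, and 4 by DESeq2) and 5 lower adjusted over the list alone. Its leading members were Eci1 (-0.15, SE 0.034), Cpt1b (-0.18, SE 0.042), Echs1 (-0.15, SE 0.038) and Cd36 (-0.14, SE 0.040), and without cKO replicate 1 the call was lost (median -0.0454, adjusted p = 0.0611). The sarcomere list had a median of -0.0206 with 0 of 33 members called over all genes (7 at an unadjusted p under 0.05, and 2 by DESeq2) and 1 lower adjusted over the list alone, and Myh6 (0.19, SE 0.082), Myh7 (-0.15, SE 0.083), Myl2 (-0.02, SE 0.076) and Myl7 (-0.05, SE 0.099) did not pass. The trabecular gene Bmp10 had 0.22 (SE 0.092) and the compact-zone gene Hey2 -0.35 (SE 0.081, adjusted p = 0.0763 by edgeR with Benjamini-Hochberg adjustment).

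Markers of macrophages and other leukocytes were higher as a list, with a median of 0.321 (adjusted p = 7.06e-05 by camera, and an adjusted p of 0.359 with an estimated correlation). Of 20 tested members 1 was higher over all genes, the complement component C1qb (log2 0.45, SE 0.082), and 4 were higher and 1 lower adjusted over the list alone. C1qc (0.42, SE 0.095) and Cd68 (0.42, SE 0.12) were among the higher members and the mannose receptor Mrc1 (-0.21, SE 0.051) was the lower. Markers of endothelium, epicardium, fibroblasts, smooth muscle, atrial myocardium, neural crest and red cells were not called, with medians from -0.294 for red cells to 0.0264 for fibroblasts. The red cell list (adjusted p = 0.155 by camera, and an adjusted p of 0.874 with an estimated correlation) was called lower without control replicate 1 (median -0.526, adjusted p = 3.72e-08), and its median was -0.113 without control replicate 3.

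Lists for the nuclear envelope, ESCRT-III and membrane repair, and DNA repair were not called. Of 23 nuclear envelope genes 0 passed over all genes (5 at an unadjusted p under 0.05, and 2 by DESeq2) and 3 were higher adjusted over the list alone. Lmna, the A-type lamin, had 0.16 (SE 0.045, adjusted p = 0.109 by edgeR with Benjamini-Hochberg adjustment), Emd 0.09 (SE 0.039), Lemd3 -0.09 (SE 0.042) and Banf1 0.05 (SE 0.044). The ESCRT-III partner Chmp7 had 0.05 (SE 0.033). Of 21 ESCRT-III and membrane repair genes and of 30 DNA repair genes 0 were called by edgeR or DESeq2 over all genes and 0 adjusted over the list alone, with 1 in each list at an unadjusted p under 0.05. The interferon and DNA-sensing list held 0 of 28 called by edgeR or DESeq2 over all genes and 0 adjusted over the list alone (3 at an unadjusted p under 0.05), and the cGAS gene Mb21d1 (-0.23, SE 0.13) and the STING gene Tmem173 (0.04, SE 0.090) did not pass. Camera did not call this list (median 0.0896, adjusted p = 0.267, and an adjusted p of 0.948 with an estimated correlation). It was called higher by camera without control replicate 1 (median 0.269, adjusted p = 0.0303) and without cKO replicate 3 (0.176, 0.0102), while the median was -0.00319 within F169.

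Cell cycle genes of G2 and mitosis were slightly higher as a list (median 0.0458, adjusted p = 0.0035 by camera, and an adjusted p of 0.84 with an estimated correlation), with 0 of 32 members called over all genes (11 at an unadjusted p under 0.05, and 4 by DESeq2) and 5 adjusted over the list alone. Ccnb1 (0.24, SE 0.050) and Cenpa (0.23, SE 0.050) led it, and Mki67 had 0.10 (SE 0.059). Cytosolic ribosomal proteins had a median of 0.0527 (adjusted p = 0.0035 by camera, and an adjusted p of 0.748 with an estimated correlation) and 0 of 24 members called by edgeR or DESeq2 over all genes or adjusted over the list alone (4 at an unadjusted p under 0.05). Without the 2 Xist-expressing libraries neither list was called (medians 0.0286 and 0.0191, adjusted p = 0.189 and 0.138). With Y-linked expression as a term neither was called either (medians 0.0275 and 0.0172, adjusted p = 0.2 and 0.177). The mitotic list was also not called within F169 (median 0.0423, adjusted p = 0.0867) and without control replicate 3 (0.0401, 0.103) or cKO replicate 3 (0.0288, 0.0922), and the ribosomal list without control replicate 2 (0.0312, 0.102).

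In all, camera called 11 of 39 lists, 9 higher and 2 lower, and 0 with an estimated correlation, where 3 lists had an unadjusted p under 0.05; fry called 1. Of the 35 ways to part the 7 libraries into 3 and 4, 17 called at least 11 lists, so the number of lists does not set the genotypes apart from other groupings. Counting the real one, a camera p as small as the real one came from 1 of the 35 splits for p53 targets, 2 each for the unfolded protein response and ATF4 targets, and 3 each for ERK targets, cardiac transcription factors and macrophages. It came from 4 splits for immediate early genes, 6 for ribosomal proteins, 7 each for fetal markers and fatty acid oxidation, and 15 for mitosis. Only the real split gave a median as far from 0 for p53 targets, the unfolded protein response, ATF4 targets and cardiac transcription factors. The same held for fetal markers, immediate early genes and macrophages. Such a median came from 2 splits for fatty acid oxidation, 3 each for ERK targets and ribosomal proteins, and 17 for mitosis. In 5 lists, none of them called, the median, the mean and the direction of the test differed in sign.

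**Figure D3:**
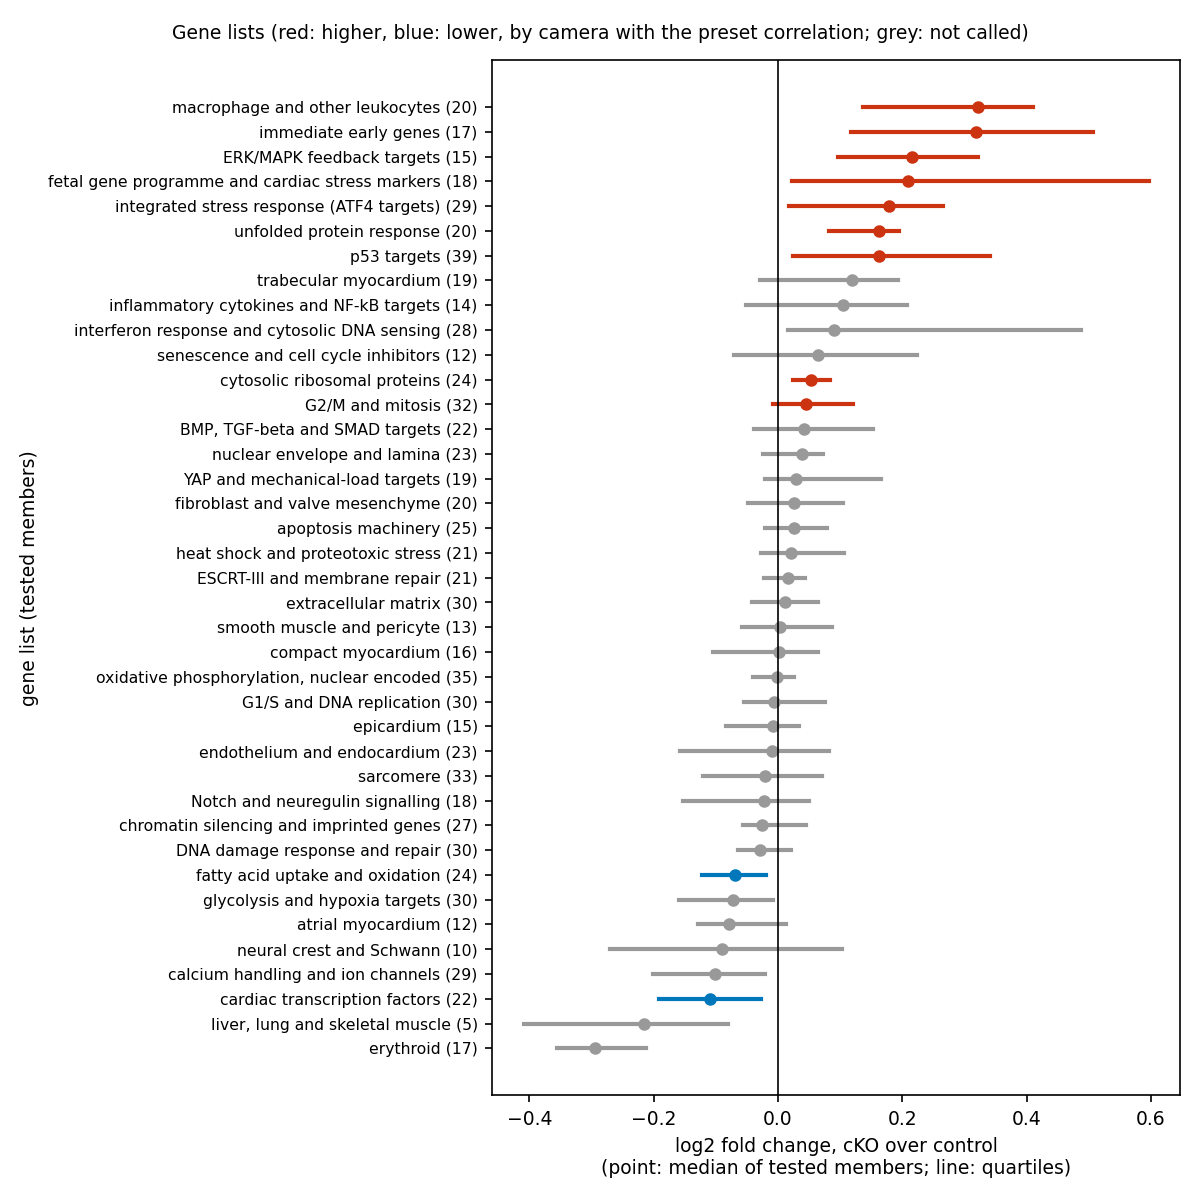
Median (point) and quartiles (line) of the log2 fold change of cKO over control (horizontal axis) for the tested members of the 39 gene lists (vertical axis, tested members in parentheses), in red or blue where camera with the preset correlation called the list higher or lower. Macrophage markers have the highest median, 0.321, and cardiac transcription factors the lower median of the 2 lists called lower, -0.11.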

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

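The tests of explanations for the p53 pattern and of other groupings of the libraries, and the estimated correlation for the difference between F codes, were chosen after the results had been seen. In 4 of the 96 named genes tested for it, 1 cKO library lay far from the other 3, and chance gives about 1 in 20. Nog was lower in cKO replicate 1, at 3.60 CPM against 4.45 to 4.47 in the others. Ctgf was higher in cKO replicate 2, at 309 CPM against 224 to 238. Banf1 was lower in cKO replicate 1, at 116 CPM against 126 to 127. Tmem173 was lower in cKO replicate 3, at 7.27 CPM against 7.57 to 7.62.

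The cKO effect differed between the libraries coded F191 and F169 for 2 genes, by an interaction term in edgeR's quasi-likelihood test. F191 holds 1 control and 1 cKO library, which the test assumes to vary like the others, so each difference rests on that pair. The pair also differs in sex, with Xist at 0.337 CPM in control replicate 3 and 1102 CPM in cKO replicate 4. For Wdfy1 the log2 difference of effects was 1.525 (SE 0.103, adjusted p = 0.00958 with Benjamini-Hochberg adjustment). Its level was 56.3, 57.0 and 31.2 CPM in control replicates 1 to 3 and 35.7, 32.3, 32.5 and 53.1 CPM in cKO replicates 1 to 4. For Tmem254c the difference was 1.722 (SE 0.158, adjusted p = 0.0466 by edgeR with Benjamini-Hochberg adjustment), with control replicate 3 at 6.15 CPM and the other libraries between 21.1 and 25.1 CPM. Tmem254c overlaps near-identical copies (Tmem254a and Tmem254b), so its counts are uncertain.

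Camera with the preset correlation also called the difference between F191 and F169 for 7 lists, on the same pair of unequal sex. With an estimated correlation it called 0 lists, with an adjusted p of 0.982 for each of the 7, and 1 list had an unadjusted p under 0.05. At the preset correlation the fitted effect was higher in F191 for interferon response and DNA sensing (adjusted p = 3.49e-06), epicardium (0.000462) and fetal and stress markers (0.00897). It was lower in F191 for atrial myocardium (1.29e-05), trabecular myocardium (8.03e-05), red cells (0.000143) and calcium handling and channels (0.0247).

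The number of genes called was not reached by any other grouping of the libraries. Only 1 of the 35 splits, the real one, called as many as 162 genes, and the highest of the others called 9. This argues against chance for that count at a share of 0.05, although 1 of 35 is the smallest share possible. The other splits mix the genotypes, so any genotype difference widens their spread and lowers their counts. The real split also parts the libraries unequally by sex. For the number of lists chance cannot be excluded, since 17 of the 35 splits called as many as the 11 of the real one and the highest of the others called 17. For the p53 targets alone, 1 of the 35 splits, the real one, gave a camera p as small (3.51e-10). The smallest p in the other splits was 1.26e-08 and the median farthest from 0 in them was 0.132 in size, against 0.162, so other groupings also gave this list small p-values. Since 39 lists were ranked over the same 35 splits, 1 list ranking first in the real split can arise by chance. Chance is therefore not excluded for the p53 list either. For the other 10 called lists between 2 and 15 of the 35 splits gave a p as small. The smallest p in the other splits was 1.42e-15 for mitosis, 4.28e-13 for ERK targets and 4.63e-12 for immediate early genes. By camera's p, chance cannot be excluded for any of these 10 at a share of 0.05. By the median, only the real split lay as far from 0 for the unfolded protein response, ATF4 targets and cardiac transcription factors. The same held for fetal markers, immediate early genes and macrophages, and for the uncalled nuclear envelope and senescence lists. The margin was narrow for cardiac transcription factors (0.11 against 0.108 in size).

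The p53 targets were higher as a list in cKO ventricle, with 8 of 39 members called and 31 not, at a camera adjusted p of 1.37e-08 and an adjusted p of 0.359 with an estimated correlation. The unequal sex of the libraries is argued against as the whole cause, since the list median was 0.169 without the 2 Xist-expressing libraries and 0.162 with them, although only 2 of the 8 called members kept their call with those fewer libraries (Cdkn1a had 0.76, SE 0.0899, before and 0.80, SE 0.109, after). Of the 8 called members 7 lie farther than 5 Mb from Lemd2 or on other chromosomes, which decides nothing on passenger variants around the floxed locus, since both groups are labelled with floxed alleles. Cre recombinase itself cannot be told apart from loss of Lem2, since 0 control libraries are labelled with the Cre transgene, and Cre activity may induce p53 targets through DNA breaks. Loss of Lem2 therefore stays a hypothesis beside it.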

How the results depend on the processing

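Alternatives with F169 alone, Y-linked expression as a term, the block and single libraries left out were set before the data were examined, and the one without the 2 Xist-expressing libraries was chosen after seeing the data. Lemd2 in cKO against control kept its fall and its call in every alternative, from -1.19 to -1.007 on the log2 scale. The 162 genes called became 637 with DESeq2 (388 higher and 249 lower, with 2601 adjusted p-values not given), of which 157 were shared, 20 within F169, 20 with the Y-linked term (17 shared), and 17 without the 2 Xist-expressing libraries (15 shared). With single libraries left out they ran from 28 to 133. Fewer libraries and residual degrees of freedom go with several of the smaller counts. The F code as a term called 214 genes with 4 residual degrees of freedom, as many as the Y-linked term left. For the Y-linked term itself 10 genes were called, 8 of them on the X or Y chromosome. That term overlaps with genotype, since all 3 controls carried Y-linked expression, and otherwise the cause of the smaller counts was not tested. The replicate numbers gave no sign of pairing, since deviations from the group means correlated at 0.045, -0.093 and -0.091 in same-numbered libraries. With the replicate block 13 genes were called (12 shared, 2 residual degrees of freedom). For a control and a cKO library with the same F code these correlations ran from -0.093 to 0.244, against -0.216 to 0.077 across codes. A shared litter or batch behind the F code is thus not excluded, and the main test has no term for it. Size factors, upper-quartile factors, no filter, limma-voom and the F code as a term gave 157 to 214 genes. The 39 other called genes named kept their direction in each alternative that gave them an adjusted p, and 6 to 39 of them kept their call. Lists called were 0 with an estimated correlation and 1 by fry, against 11. Of the 28 lists not called, 9 were called by camera in some of 16 alternatives: YAP targets in 7, trabecular myocardium and BMP targets in 5 each, calcium handling in 4, glycolysis in 3, interferon and inflammatory genes in 2 each, and heat shock and red cells in 1 each. Directions reversed for uncalled genes: Myl2 without control replicate 1 (0.004767) or cKO replicate 1 (0.05208; range with single libraries left out -0.05658 to 0.05208), Tmem173 without control replicate 1 (-0.006787; range -0.006787 to 0.1395), and Myl7 within F169 (0.06195), with the Y-linked term (0.006463), with the block (0.02137), without cKO replicate 4 (0.02777; range -0.1297 to 0.02777) and without the 2 Xist-expressing libraries (0.008751), and the cause was not tested. The F191 libraries alone were not run, as 1 per group leaves no residual degrees of freedom. At these depths 61.2% of the smallest simulated changes were called, so smaller differences can be missed.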

Other observations

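Genes named here beyond the naming rule were chosen after their values were seen, and so were the tests of explanations for the Gt(ROSA)26Sor and macrophage patterns, except that of the genes around Gt(ROSA)26Sor. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 5 genes known from leukocytes and in no list were among those called higher, and were picked for their rise. The pore-forming protein Mpeg1 rose from 13.1 ± 1.37 to 21.6 ± 1.19 CPM (log2 0.72, SE 0.079, adjusted p = 0.00534 by edgeR) and the lysosomal protease Ctss from 7.46 ± 0.863 to 11.2 ± 0.683 CPM (0.59, SE 0.092). The anaphylatoxin receptor C3ar1 rose by 0.47 (SE 0.093), and Lair1 (1.41, SE 0.27) and Ly9 (1.47, SE 0.29) rose from 0.422 and 0.171 CPM. Other leukocyte markers did not pass, among them Cd14 (0.41, SE 0.35), Fcgr3 (0.09, SE 0.10), Itgam (-0.04, SE 0.19), Pf4 (-0.13, SE 0.16) and Lyve1, which vessels also make (-0.21, SE 0.16). All 3 GADD45 genes, which respond to growth arrest and DNA damage, rose, Gadd45a by 0.58 (SE 0.10), Gadd45b by 0.89 (SE 0.072) and Gadd45g by 0.73 (SE 0.12). Gadd45a overlaps E230016M11Rik on the opposite strand, so its counts are uncertain. That gene had a mean of 0.362 CPM, against 3.23 CPM for Gadd45a in control and 4.83 CPM in cKO.

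Single called genes that were higher included the integrin subunit Itgav (0.43, SE 0.042), the hyaluronan receptor Cd44 (0.37, SE 0.038), the EGF-family ligand Hbegf (0.41, SE 0.068), Hmga2 (0.32, SE 0.037), Igf2bp1 (0.26, SE 0.036) and Odc1 (0.36, SE 0.052). Bcl2 (0.26, SE 0.047) was the 1 called member of the apoptosis list, in which 24 of 25 members were not called (adjusted p = 0.369 by camera). The potassium channel Kcnn2 fell by 0.37 (SE 0.060) beside Kcnn1, while Kcnn3 had -0.05 (SE 0.16). Kcnn2 overlaps A330093E20Rik on the opposite strand, so its counts are uncertain. That gene had a mean of 0.295 CPM, against 18.4 CPM for Kcnn2 in control and 14.3 CPM in cKO. Rbm20, a splicing factor of titin, fell by 0.27 (SE 0.053).

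Gm14296 and 2210418O10Rik share 1 stretch of chromosome 2 and nearly equal values, so their reads cannot be assigned. Gm14296 lay at 6.42 and 6.02 CPM in cKO replicates 1 and 2 and between 11.1 and 13.0 CPM in the other 5 libraries.

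Gt(ROSA)26Sor fell in cKO to a mean of 0.512 times the control mean, with single cKO libraries from 0.453 to 0.565 times (SD 0.0465, n = 4). A change of the whole region of chromosome 6 is argued against, since the 30 tested genes within 1 Mb had a median log2 fold change of -0.00457 (quartiles -0.113 and 0.0832) and 0 of them were called by edgeR (9 at an unadjusted p under 0.05, and 1 by DESeq2). Unequal sex is argued against too, since the log2 fold change without the 2 Xist-expressing libraries was -0.9591. A candidate explanation that stays open is that 1 of 2 copies of the locus is silent in each cKO embryo, which was drawn from these same ratios and has no independent test. The labels name no allele at this locus, and whether loss of Lem2 lowers this transcript was not tested apart from the other differences between the groups.

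The macrophage markers were higher as a list in cKO ventricle, with 1 of 20 members called over all genes, at a camera adjusted p of 7.06e-05 and an adjusted p of 0.359 with an estimated correlation. Fewer cardiomyocytes in the tissue is argued against as the whole cause, because the 20 macrophage markers changed by 0.242 more than 70 markers of endothelium, epicardium, fibroblasts and smooth muscle (mean log2 CPM, SE 0.0839, exact two-sided permutation p = 0.0286, the smallest possible). The macrophage list was taken up for its rise, so that p-value is partly set by the choice. Those 70 other markers had a median log2 fold change of 0.00277, and the sarcomere members -0.0206. That median does not mean that no marker moved. Unadjusted p was under 0.05 by edgeR for 10 of 23 endothelial, 2 of 15 epicardial, 0 of 20 fibroblast and 3 of 13 smooth muscle members. Adjusted over the list alone, 2 endothelial members were higher and 1 lower. More macrophages of an unchanged kind stays open. The members did not change by one amount (Cochran Q = 103 on 19 degrees of freedom), but Mrc1 and Lyve1 are also made by vessels and the members come from the same 7 libraries, so unequal changes decide nothing.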
